A study of Zea mays with 12 samples.

How the data were processed

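RNA was measured in 6 samples of maize shoot apices, 3 from tml1;tml2 mutants and 3 from segregating wild types. The labels state 3 individual apices in the extraction, an RNA integrity number of 9 and paired reads of 150 bases. Whether each sample pools 3 apices or each is 1 apex is left open by that wording. Each sample has 2 sequencing runs, which the labels call technical replicates. STAR, Salmon and DESeq2 are named in the submitters' processing notes without versions. The part each played in alignment, the genome build and the filters are not given in the sources used here. The prefix of the IDs in the gene table is read here as that of the B73 version 4 gene models.

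The deposited gene table gives 3 kinds of value for each of the 12 run columns. The authors deposited estimated counts per gene and run, which need not be whole numbers. They also deposited TPM (transcripts per 1000000 transcripts), which sums to 976334 to 981645 per run over the listed genes, so a small part of what was quantified lies outside the table. The third kind is the average transcript length per gene and run, in bases. A second table holds the authors' own comparison per transcript, limited to adjusted p of up to 0.05. Its deposited values are the mean normalized signal per transcript, the log2 fold change with its standard error, the Wald score, and the p-value with its adjusted form, per the file headers. Columns of per-sample values left unused numbered 0.

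Samples were grouped by the genotype in their titles. Estimated counts of the 2 runs were summed per sample and rounded to whole numbers. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), two-sided, with TMM scaling and edgeR's expression filter by group, without covariates. P-values were adjusted by Benjamini-Hochberg over the 22772 genes tested, with a threshold of 0.05. The prior degrees of freedom were 2.53 beside 4 residual ones. Log2 CPM used a prior count of 2. Standard errors of log2 fold changes are approximate, taken from the edgeR fit. The p-values set the difference between genotypes against the spread among samples of one genotype.

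Alternatives set before the data were examined were DESeq2 1.42.0 on the 6 sums and on the 12 run columns, voom and log2 TPM fits with limma 3.58.1 (pseudocounts 1 and 0.1, TPM of at least 1 in at least 3 samples), median-of-ratios scaling, no filter, a filter of 1 CPM in 3 samples, each run alone, a replicate block, a transcript length offset, a minimum fold of 1.2, and each sample left out. Added after the data were seen were a robust fit, edgeR's likelihood ratio test, 1 surrogate variable from sva 3.50.0, the leave-out fits of DESeq2, the genes detected in one genotype alone, the counts of low-p and called genes in windows of 100 and 10 consecutive tested IDs, and the test of transcript length with limma.

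Genes to be named were fixed by rule before the data were examined: the targeted genes, then genes past the threshold with no overlap between genotypes and a mean of at least 1 CPM in the higher group. With fewer passing, the rule took the lowest p in each direction under the other conditions, and without gene names 2 IDs each way. None of the 39324 IDs, a match of 0, was found in the reference gene table of 49888 genes on assembly Zm-B73-REFERENCE-NAM-5.0. The 27 gene lists fixed beforehand, which cover hormones, vascular and leaf regulators, cell cycle, photosynthesis, stress and markers of other tissues, therefore had 0 lists with a measured member, and no list was tested.

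The tests were checked on simulated mutant and wild-type counts with 200 changed genes. With the spread estimated per gene, edgeR recovered 3 of 67 genes changed 2-fold, 34 of 67 changed 4-fold and 52 of 66 changed 8-fold among 22444 genes, with 5 false calls. DESeq2 recovered 14, 57 and 63 of the same genes among 22772, with 77 false calls. With a small spread, edgeR recovered all of 67, 67 and 66 with 9 false calls, and DESeq2 65, 67 and 66 with 12. The length test recovered 200 of 200 planted genes among 21744, with 8 false calls. Run totals were 13123537 to 16520755 counts, and the TMM factors ranged from 0.919 to 1.04.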

Results

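Gene expression was measured by strand-specific RNA sequencing in shoot apices of maize inbred line B104. The apices held the shoot apical meristem, which is the dome of dividing cells that forms leaves, together with the leaf primordia of plastochrons 0 to 5 and the leaf sheath. Plastochron numbers count primordia from the youngest outward. Seedlings were dissected after 7 days, and root, embryo and coleoptile were removed. The tml1;tml2 mutants carried loss-of-function alleles made by CRISPR/Cas9 editing in both TOO MANY LATERALS genes. Their titles mark them as HMZ, read here as homozygous. The wild types were siblings that segregated from the same material. Each genotype had 3 biological samples, numbered 2, 3 and 4 in the labels, and each of the 6 samples was sequenced in 2 runs. The table of estimated counts held 39324 gene IDs, of which 11305 had 0 counts in every sample and 22772 passed the filter for testing. Summed over both runs, the wild types held 29616910, 29504673 and 31980554 counts and the mutants 29568803, 27213045 and 29968412. At this depth, 3 counts correspond to 0.0971 to 0.106 CPM (counts per 1000000 counts of a sample). Such a floor covers counting error only.

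The 2 runs of a sample differed by somewhat more than counting noise, with a median chi-square per gene of 0.681 to 0.721 where counting noise alone gives 0.455, and a mean of 3.43 to 3.94 where it gives 1. Between samples the median was 6.06 to 19.3 within a genotype and 6.87 to 34.8 across genotypes, so no pair of the 6 samples looked like one library. The runs of each sample were summed. The biological coefficient of variation was 0.363 among wild types, 0.404 among mutants and 0.0907 between runs. The first principal component of log2 CPM held 46% of the variance and the second 20.2%. On the first component, wild type 2 and wild type 4 scored −84 and −64.5, mutant 2 scored −3.21, wild type 3 scored 9.88, mutant 3 scored 26.2 and mutant 4 scored 116. Wild type 3 and mutant 2 lay together on the second component, at −58.2 and −59.5. The genotypes were therefore not fully parted on either component.

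**Figure D1:**
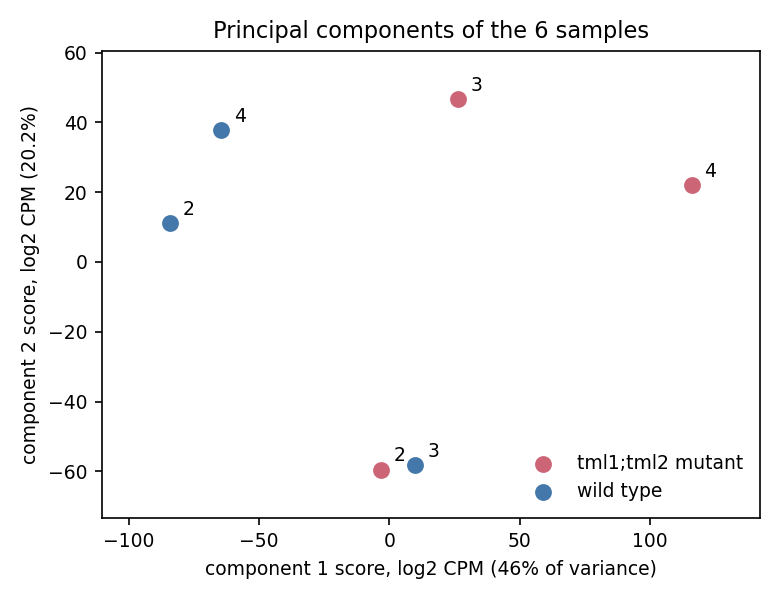
Principal components of log2 CPM for the 6 samples, with component 1 (46% of variance) on the x axis and component 2 (20.2%) on the y axis. Each point is a sample with its number from the labels, blue for wild type and red for the tml1;tml2 mutant, and mutant 2 lies beside wild type 3.

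The comparison of mutant with wild type asked which genes depend on the TML genes in the tissue where leaf veins are laid down. The genes with the lowest p in each direction differed by 2.62-fold to 13.2-fold. Zm00001d029654 was at 47.6 ± 25.7 CPM in the mutant and 3.6 ± 0.502 CPM in the wild type (SD, n = 3 each), a difference of 13.2-fold. Zm00001d048085 was at 67.1 ± 9.42 CPM in the mutant and 25.6 ± 2.35 CPM in the wild type, a difference of 2.62-fold. In the other direction, Zm00001d031934 was at 2.57 ± 0.527 CPM in the mutant and 19.2 ± 5.5 CPM in the wild type, a difference of 7.48-fold. The most abundant of these genes, Zm00001d048709, was at 284 ± 24.9 CPM in the mutant and 894 ± 115 CPM in the wild type, a difference of 3.15-fold. Genes were named only where the 3 mutant values did not overlap the 3 wild-type values. Zm00001d048709 was 1 of 6 DESeq2 calls within 9 consecutive ID numbers, a run chosen after its values were seen, and all 6 had lower values in the mutant.

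**Figure D2:**
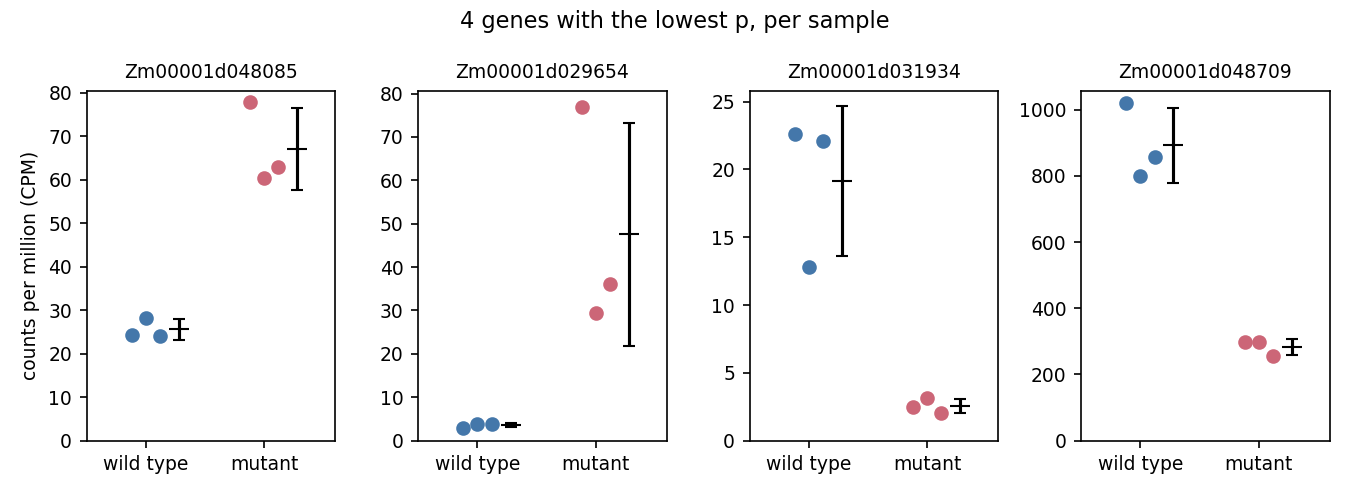
CPM of 4 genes in each of the 6 samples, with the y axis of every panel starting at 0. Points are samples, blue for wild type and red for mutant, and the black bar beside each group is the mean ± SD (n = 3); genes were chosen among those whose 3 mutant values do not overlap the 3 wild-type values.

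The log2 fold changes, mutant over wild type, were 3.72 (SE 0.42) for Zm00001d029654, 1.39 (SE 0.16) for Zm00001d048085, −2.90 (SE 0.31) for Zm00001d031934 and −1.66 (SE 0.19) for Zm00001d048709. In edgeR's quasi-likelihood test none of the 4 passed the threshold, each with an adjusted p of 0.27. With DESeq2 on the same 6 samples all 4 passed, with adjusted p of 4.1e-15, 9.8e-10, 6e-14 and 9.2e-17 in the same order. The files do not pair these IDs with gene names, so what the genes encode is not given here. For the same reason tml1 and tml2 themselves were not analysed here, and the genotype of each sample rests on its label.

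Across the transcriptome, edgeR called 0 of 22772 genes at an adjusted p of 0.05, and the lowest adjusted p was 0.271. At an unadjusted p under 0.05, edgeR gave 2784 genes where 1139 would be counted by chance alone, 1575 with higher and 1209 with lower values in the mutant. Splits of the 6 samples that mix the genotypes gave up to 2953 genes, with a median of 515. Each such split still parts the genotypes unequally, so these splits cannot tell whether the excess over 1139 comes from genotype. Of the 2784 edgeR genes 56.6% had higher values in the mutant. The share was 51.8% with limma-voom on the scaled counts and 75.2% with limma on log2(TPM + 1) without further scaling, each at its own unadjusted p under 0.05. The TPM fit also had another filter, and the median log2 fold change of all genes was 0.13 in it. The 3 mutant values lay entirely above or below the 3 wild-type values for 4400 genes, 19.3% of those tested, where chance gives 10%. Setting wild types 2 and 4 with mutant 2 against the other samples, a split that mixes the genotypes, gave 4747 such genes. Of these 4400 genes, 2344 were higher and 2056 lower in the mutant. DESeq2 on the 6 samples called 658 genes, 463 higher and 195 lower in the mutant. All 630 of these that edgeR tested had an unadjusted edgeR p under 0.05. Splits that mix the genotypes gave up to 863 DESeq2 calls, with a median of 28. In the simulated counts with the spread estimated per gene, DESeq2 made 77 false calls and edgeR 5. The adjusted p-values of DESeq2 can therefore be too low at this spread. The DESeq2 count of 658 was 185 without wild type 2, 309 without wild type 4, 428 without mutant 4, 1064 without mutant 2, 1138 without mutant 3 and 1344 without wild type 3. The excess of higher over lower calls shrank to 581 against 557 without mutant 3 and 241 against 187 without mutant 4. It remained without wild type 2, at 136 against 49, and without wild type 3, at 941 against 403. Without wild type 4 it was 232 against 77, and without mutant 2 it was 796 against 268. The edgeR count of 2784 was 1348 without wild type 2, 1475 without wild type 4 and 1693 without mutant 4, and edgeR called 0 genes in each case. An exact permutation test of one gene with 3 samples against 3 cannot go under p = 0.1.

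The share of genes that stood apart was higher among abundant genes. Among the 7591 most abundant genes, with means of 32.3 to 4020 CPM, 14.4% had an unadjusted edgeR p under 0.05, and the median absolute log2 fold change was 0.25. Among the 7590 genes of middle abundance the share was 12.6%, with a median of 0.26. Among the 7591 least abundant genes, with means of 0.205 to 7.77 CPM, the share was 9.68% although the median absolute log2 fold change was 0.44. The low-abundance genes at that threshold were more often higher in the mutant, 461 against 274, than the high-abundance genes, 574 against 521. The difference between these shares was not tested.

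A small set of genes was read in one genotype alone. With 0 counts in all 3 samples of one genotype and at least 0.5 CPM in every sample of the other, 5 genes were detected in the mutant only and 2 in the wild type only. Their means in the genotype that had them were 1.45 to 9.5 CPM, at least 14.3-fold to at least 93.5-fold above a floor of 3 counts per sample. With a minimum of 1 CPM the count was 3. The highest of the 9 splits that mix the genotypes gave 4 genes at 0.5 CPM and 3 at 1 CPM. DESeq2 on the 6 samples called all 7, and the lowest edgeR adjusted p among them was 0.33.

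The authors' deposited table lists 7216 transcripts of 6204 genes at an adjusted p of up to 0.05 by DESeq2. Its header does not name the numerator of the fold change. In the authors' deposited table the log2 fold change of 6487 of 7058 transcripts (91.9%) had the opposite sign to mutant over wild type as computed here from the gene counts, so it is read as wild type over mutant. On that reading the authors' deposited table gives 3851 transcripts as higher and 3365 as lower in the mutant. For Zm00001d048709 the authors' deposited table gives a log2 fold change of 1.67 (SE 0.0877) for transcript T002, and for Zm00001d031934 it gives 2.94 (SE 0.236) for T001, both lower in the mutant. For Zm00001d029654 the authors' deposited table gives −3.20, −5.47 and −8.03 for 3 transcripts, all higher in the mutant. The table comes from the same libraries and is not independent evidence.

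Of the 658 genes called by DESeq2 on the 6 samples, 629 were in the authors' deposited table, where 164 would be shared by independent lists. Both lists come from DESeq2 on the same libraries, so a large overlap was bound to arise and is no evidence about the genotypes. DESeq2 run on the 12 run columns, as if every run were a separate sample, called 5993 genes, 9.11 times as many as with summed runs. Of these, 4712 were in the authors' deposited table, where independent lists would share 1493. For 2582 transcripts whose mean in the authors' deposited table was within 2% of the gene's mean count per run, the median ratio of the table's SE to that of the 12-column fit was 0.994. The median ratio to the SE of the 6-sample fit was 0.635. Runs of one library vary less than samples do, so the 5993 calls are not a test of the genotypes. Over genes with 1 listed transcript, the mean in the authors' deposited table had a median ratio of 0.978 to the mean count per run. That ratio and the SE ratios argue against summed runs in the authors' deposited table, for the transcripts they cover. How runs were handled there is not given in the sources used here. If they were counted as samples, the same limit holds for its 7216 transcripts and their SEs.

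**Figure D3:**
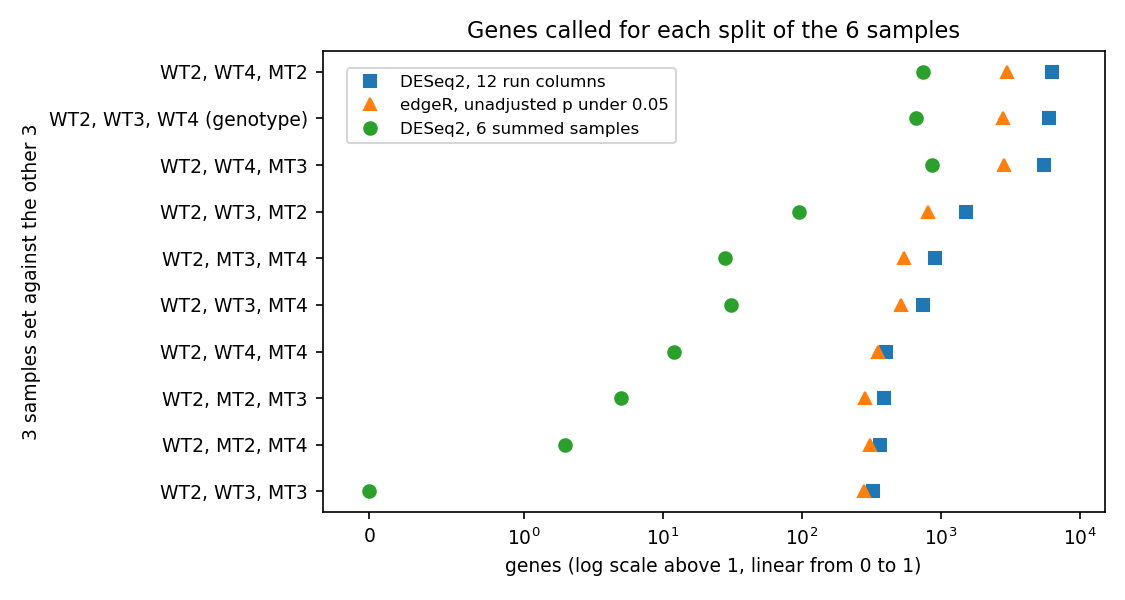
Number of genes for each of the 10 ways to set 3 of the 6 samples against the other 3, on a log axis that is linear from 0 to 1. Squares are DESeq2 calls with 12 run columns, triangles edgeR genes at an unadjusted p under 0.05, and circles DESeq2 calls with 6 summed samples; the split by genotype gives 5993, 2784 and 658.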

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

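The fits by likelihood ratio, robust fitting and surrogate variable, the DESeq2 leave-outs, the alternatives for the count at unadjusted p, and the counts of genes off in one genotype and of transcript lengths were chosen after the results were seen. The count of 0 from edgeR's quasi-likelihood test became 658 with DESeq2 on the 6 samples, 5993 with DESeq2 on the 12 run columns and 383 with edgeR's likelihood ratio test; it was 0 in the other alternatives, including each leave-out (0 to 0). The quasi-likelihood test allows for uncertainty in each gene's spread and the likelihood ratio test does not. The 2784 genes at unadjusted p under 0.05 became 9141 with DESeq2 on the 12 run columns, where DESeq2 on the 6 samples gave 3754, and 1286 with edgeR and 1 surrogate variable, and ranged from 1348 to 3639 over the leave-outs. That count was 1348 without wild type 2, 1475 without wild type 4 and 1693 without mutant 4. DESeq2's 658 calls ranged from 185 to 1344 over the leave-outs: 185 without wild type 2, 309 without wild type 4, 428 without mutant 4, 1064 without mutant 2, 1138 without mutant 3 and 1344 without wild type 3. The overlap with the authors' deposited table was 0, 629 and 4712 genes for edgeR, DESeq2 on 6 samples and on 12 run columns. The replicate block gave 0 calls by edgeR, 1790 genes at unadjusted p under 0.05 and a lowest adjusted p of 0.53. Deviations of same-numbered samples correlated at 0.22, −0.27 and −0.18, and not every sample correlated best with its own number. Taken from the mean of only 3 samples per genotype, these deviations cannot decide whether the numbers pair the samples. The 7 genes off in one genotype became 3 at a minimum of 1 CPM. The 1 gene whose transcript length differed became 0 at a mean TPM of at least 5 and 0 to 0 over the leave-outs. The 4 named genes were past the threshold in 3 of 21 alternatives; they kept their direction in all 21, which their choice by low p without overlap left little room to change. Beyond the fewer samples of a leave-out, the cause of these shifts was not tested. Gene list alternatives were not run, since no list had a measured member. Depth limits the least abundant genes, whose floor is 0.0971 to 0.106 CPM.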

Other observations

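The tests in this part were chosen after the results were seen, except those of thinning, transcript length bias and scaling on the first component and the median count over other splits with run columns. Average transcript length, which moves when a gene shifts between long and short transcripts, was compared for 21744 genes with a mean TPM of at least 1. One gene passed limma's test, Zm00001d037579, named after its value was seen. Its average transcript length was 417 ± 3.9 bases in the mutant and 513 ± 7.92 bases in the wild type (SD, n = 3 each), and limma gave an adjusted p of 0.047. It was a weakly expressed gene, at a mean TPM of 1.68, and its expression did not pass edgeR's test at an adjusted p of 0.42. With any 1 of the 6 samples left out, limma called 0 genes. A split that mixes the genotypes, wild types 2 and 4 with mutant 2 against the other samples, also gave 1 call. At an unadjusted p under 0.05 with all samples, limma gave 877 genes where 1087 would be counted by chance. In the authors' deposited table, 199 of the 802 genes with more than 1 listed transcript had transcripts of both signs.

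With 10 splits of the 6 samples, the splits are too few for a share under 0.05. The split by genotype gave 2784 genes at an unadjusted edgeR p under 0.05, and the highest other split gave 2953, so 3 of the 10 splits gave as many. For DESeq2 on the 6 samples the split by genotype gave 658 and the highest other 863, again with 3 of 10 as large. In each case the other splits with as many genes set wild types 2 and 4, with mutant 2 or mutant 3, against a side that held mutant 4. For genes whose 3 values on one side did not overlap the other 3, the split by genotype gave 4400 and the highest other 4747. For genes off on one side it gave 8 against 5 in the highest other split at 0.2 CPM, 7 against 4 at 0.5 CPM and 3 against 3 at 1 CPM. For transcript length it gave 877 genes at an unadjusted limma p under 0.05, against 831.

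The first principal component set mutant 4 against wild types 2 and 4. A difference in library size is argued against by the order of the totals, since the 29968412 counts of mutant 4 lie between the 29616910 of wild type 2 and the 31980554 of wild type 4, which both sit at the other end of the component. Transcript length bias is argued against by a Spearman correlation of 0.074, across genes, between loadings and average transcript length. Thinning to the smallest total and median-of-ratios scaling each left a rounded correlation of 1 with the original scores, but thinning removed at most 14.9% of a library's counts and the factors differ from TMM by at most 0.86%, so neither decides and the scaling of the libraries stays open. The number of genes with counts in run 1 rose in the same order as the scores, from 24535 in wild type 2 to 25409 in mutant 4. Whether that number bears on the component or follows from it was not tested. A difference in developmental stage or in the share of each tissue in the dissection, beside genotype, was not tested, since no gene names were at hand.

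The 5993 genes called with 12 run columns may come in part from counting runs of one library as replicates. The run columns gave more calls than summed runs in 9 of the 9 splits that mix the genotypes, but this decides nothing about extra calls from counting runs of one library as replicates, since runs that vary less than samples shrink the SE in any split. The median over those splits was 741 calls, below the bound set for runs as the whole cause, while the highest was 6280, above the 5993 of the split by genotype. How much of the 5993 comes from the runs, from the genotypes or from other differences between the samples cannot be told apart.

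The lowest-p genes could come from a linked block of the genome that differs between the genotypes. The highest number of the 300 lowest-p genes within 100 consecutive tested IDs was 6, where shuffled p-values gave a median of 6 and the highest other split gave 7. In shorter windows, 10 consecutive tested IDs held up to 6 of the DESeq2 calls, Zm00001d048709 among them. Counted likewise without regard to direction, shuffled calls gave a median of 4 and a highest value of 6, and the highest other split gave 5. These 6 genes were abundant, at 400 to 2180 CPM in the wild type, and all had lower values in the mutant, with DESeq2 log2 fold changes of −1.67 to −1.21 and edgeR adjusted p of 0.27 to 0.35. A linked block that differs between the genotypes, seen as a run of calls, and joint regulation of neighbouring genes both stay open, since the run was seen before it was tested and no table used here places the IDs on chromosomes.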
